A study of Homo sapiens with 8 samples.

How the data were processed

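Poly(A)-selected RNA libraries were made from A375 cells in 4 groups of 2, with an NEBNext Ultra kit, per the labels' protocols. That kit does not mark the strand of origin. Cells grown in medium with 10% serum were transfected 24 h after seeding with empty plasmid or with plasmid carrying 1 of 3 SLNCR1 constructs, and harvested 48 h after transfection. The labels gave the group of every sample. Without strand, reads of overlapping genes on opposite strands cannot be told apart.

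The deposited data were 3 tables, each comparing a construct with vector over 56638 entries. Per the submitters' processing notes, STAR, featureCounts and DESeq were used with the hg19 genome build. Versions, settings and the gene annotation are not given in the sources used here. The signal in each table is the authors' mean over a group of reads per gene divided by size factors, per the file headers and the values. Each table was normalized on its own by the authors. The fold change in each deposited table is the ratio of the construct mean to the vector mean, and log2 was taken of it here because the deposited log2 column holds text in some cells. The p-values and adjusted p-values are those of the authors' test within each deposited table. Spreadsheet software had turned 28 identifiers into dates, 4 identifiers occur more than once, and 31126 match a current or older symbol of the reference names.

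Before the data were examined, both a plan for counts and a plan for comparison tables were written, and the tables called for the latter. The main counts of changed genes are thus those with the authors' adjusted p under 0.05, by direction. Against vector, list members said to have passed, risen or fallen are counted in the same way unless limma is named. A gene can be named if it is the target, or among the 10 largest log2 changes each way that passed with a mean of at least 50 in the higher group and a symbol among the reference names, or among up to 4 passing members of a list, or is MMP9, POU4F1, EGR1, CDKN1A, SRA1 or MITF (1 further gene fixed in this way is not reported here). Where fewer than 10 genes passed, the 10 with the lowest p could be named as values. For direct comparisons the 5 largest each way were named. Genes outside this rule were chosen after their values were seen. In the results they were RELB, and with delta-conserved LGALS3BP, NFKB2, IL11, SOD2, MMP14, DDB2, INHBA, HSPA5, PDIA6, DDIT4, ATF3, ASNS, NQO1 and MT2A, which complete small counts. The clock genes named in the closing observations, other than HLF and BHLHE41, were also chosen in this way.

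A group mean over 2 libraries is a sum of whole multiples of 2 steps, 1 for each library, so the whole reads of single libraries could be solved for. A single solution was found for 100% of genes with reads in vector, SLNCR1 and delta-conserved, and for 99.981% with the conserved region, where 6 genes had more than 1. On simulated means for 4000 genes, a single solution was found for 98.98% with 2 tables and 97.4% with 1 table, and all of these were correct. The values do not show which library is which replicate, so the deeper is called a and the other b.

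Recovered reads were normalized over all 8 libraries by median-of-ratios size factors. Differences were tested with limma 3.58.1 in R 4.3.3 (linear model over the 4 groups, moderated variances with a trend) on log2(normalized count + 1) for 16058 genes with a mean of at least 10, with Benjamini-Hochberg adjustment. The fit has 4 residual degrees of freedom and a prior worth 13.6. On this scale changes of low genes are understated. Values given as mean ± SD are over these normalized counts. Count-based models were not used on the recovered reads. Recovery and figures used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

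The limma step was tested on simulated counts for 16200 genes with a known set changed. For SLNCR1 against vector it recovered 69.7% of genes changed 1.5-fold, 85.1% at 2-fold and 98.5% at 4-fold, with 6 false calls among 174. For the conserved region the shares were 66.7%, 89.6% and 100%, with 2 false calls among 171, and for delta-conserved 63.6%, 86.2% and 96.9%, with 13 among 174. Between constructs, 28 of 359 calls were false for SLNCR1 against delta-conserved, 22 of 353 for the conserved region against delta-conserved and 16 of 353 for SLNCR1 against the conserved region.

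Gene lists fixed before the data were examined covered metalloproteinases, androgen-responsive genes, immediate early genes, MAPK output, p53 targets, interferon-stimulated genes, NF-kB and cytokines, pigmentation, dedifferentiation, extracellular matrix, TGF-beta, S phase, G2 and M phase, unfolded protein response, heat shock, cholesterol, hypoxia and glycolysis, metallothioneins and oxidative stress, ribosomal proteins, oxidative phosphorylation, mitochondrially encoded genes, histones and nuclear long noncoding RNAs. Markers of 5 other cell types were added to make 28 lists. Each was tested in the 3 comparisons by limma's cameraPR with a preset correlation of 0.01, on signed z scores of the authors' p-values for genes with a mean of at least 10, with adjustment over all 84 tests. Of these 45 passed, and none did with a correlation estimated by camera from the recovered libraries, where the residual degrees of freedom are 4. Loss of a call there also befell lists with an estimated correlation close to 0. For the direct comparisons camera with the preset correlation was run on the limma values and adjusted over its own 84 tests. On simulated SLNCR1 data over 16205 genes, 0 of 100 random lists had a p under 0.05, and a shifted list had a p of 7.23e-139. The simulated genes were independent, so this check does not cover lists of correlated genes. The estimated correlation was 0.74 for interferon-stimulated genes, 0.92 for ribosomal proteins and 0.98 for mitochondrially encoded genes. In lists of mixed direction the median, mean and test could differ in sign. This was so for metalloproteinases in all 3 comparisons, fibroblast markers with SLNCR1 and with the conserved region, leukocyte markers with SLNCR1, and pigmentation and cholesterol genes with delta-conserved.

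Overlaps were tested by two-sided Fisher's exact tests among genes with a p in both tables, beside 20 simulations of unchanged groups against the same vector libraries. Libraries of a group were compared by chi-square over genes with at least 20 reads. Transcript lengths and GC content came from GENCODE release 29 on GRCh38 and were matched by symbol. Alternatives were other thresholds, filters, pseudocounts, scalings, thinning to the smallest library, limma in place of the authors' test, leaving out each library, and other list statistics. The depth per library, given with the results, sets the precision, which for genes of a few reads, such as MMP9, is low.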

Results

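Gene expression was measured by RNA sequencing in A375 cells, a human malignant melanoma line that carries an activated BRAF kinase. The cells were transfected with an expression plasmid that was empty (vector), or that carried the long noncoding RNA SLNCR1 at full length, its conserved region alone, or SLNCR1 without that region. Each of the 4 groups had 2 libraries. SLNCR1 has been tied to melanoma invasion, to the metalloproteinase MMP9 and to the transcription factor POU4F1. The constructs thus asked which expression changes follow the RNA and which of its parts is needed. The reads assigned to genes numbered 12015394 and 11321294 in the vector libraries, 10097194 and 9090649 with SLNCR1, 11340439 and 10280144 with the conserved region, and 9187241 and 8222868 with the delta-conserved construct. Within each group the deeper library is called a and the other b.

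Libraries of a group differed by more than counting noise in all 4 groups. The chi-square per degree of freedom between libraries a and b was 2.97 for vector, 4.28 for SLNCR1, 1.28 for the conserved region and 1.58 for delta-conserved. Across genes, which are not independent replicates, the log2 levels of a pair had a Pearson correlation of 0.990 to 0.995. The first principal component held 41.3% of the variance. The vector and conserved-region libraries lay between -20.31 and -14.07 on it, and the SLNCR1 and delta-conserved libraries between 14.24 and 26.95. SLNCR1 library b stood apart on the second component (15.9% of the variance), at 24.01 against -18.11 to 4.93 for the other libraries. The labels do not say that the libraries of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

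The transfected RNA was read through LINC00511, a long noncoding RNA gene on chromosome 17. SLNCR1 is a synonym of LINC00673 in RefSeq, no entry of the deposited tables carries that name, and all 5 RefSeq transcripts of LINC00673 match transcripts of LINC00511 in GENCODE release 29. The annotation release behind the tables is not given in the sources used here, so which exons its LINC00511 entry counts is open, and no coordinates are given because the reference and the files use different genome builds. LINC00511 stood at 620 ± 4.65 normalized counts in vector cells (SD, n = 2), 869 ± 15.3 with SLNCR1, 1089 ± 62.4 with the conserved region and 1005 ± 200 with delta-conserved. In the authors' deposited table it rose by a log2 of 0.49 with SLNCR1 (adjusted p = 0.00559) and by 0.80 with the conserved region (adjusted p = 5.89e-15). For delta-conserved, the authors' deposited table gave a log2 fold change of 0.69 with an adjusted p of 0.145, and the reads of its libraries, 1038 and 689, were far apart. By limma on the recovered libraries, which pools the spread over all groups, that difference was 0.68 ± 0.10 (SE) with an adjusted p of 0.000297. LINC00511 was thus higher than in vector in all 6 libraries with a construct, by less than a doubling of the group means. Its limma call with SLNCR1 (adjusted p = 0.00441) was lost without vector library a (adjusted p = 0.062), and that with the conserved region (adjusted p = 0.00279) without vector library a (adjusted p = 0.105) or b (adjusted p = 0.254).

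With full-length SLNCR1 far more of the called genes were lower than higher. Of 33548 genes with a p-value in the authors' deposited table, 13 rose and 283 fell against vector at an adjusted p under 0.05 (885 higher and 1213 lower at an unadjusted p under 0.05). The largest falls included HLF, a PAR-domain transcription factor, from 49.9 ± 5.66 to 3.60 ± 1.98 normalized counts, and ITGAM, the integrin alpha M chain, from 67.4 ± 10.5 to 7.29 ± 1.0 (SD, n = 2). The growth factor-induced transcription factor EGR2 went from 201 ± 5.41 to 31.9 ± 1.34, and the circadian repressor BHLHE41 from 606 ± 46.8 to 108 ± 0.403. IL6, an inflammatory cytokine, had the largest increase among the named genes that rose, from 121 ± 5.17 to 242 ± 24.7.

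Further genes in the authors' deposited table with a large log2 fall were NEURL3 (-2.66, adjusted p = 3.26e-26), PLA2G4C, a phospholipase (-2.59, adjusted p = 6.34e-19), TSPAN2, a tetraspanin (-2.55, adjusted p = 2.92e-19), and PIK3IP1 (-2.52, adjusted p = 2.56e-05). The authors' deposited table also gave -2.42 for ALOXE3, an epidermal lipoxygenase (adjusted p = 3.87e-18), and -2.78 for ASNSP1 (adjusted p = 1.75e-09). ASNSP1 is a pseudogene of asparagine synthetase and may take reads of its parent, so its value is uncertain. Further increases in the authors' deposited table included log2 values of 0.60 for AKR1C1, an aldo-keto reductase, and 0.38 for CD55, a complement regulator. Others were LYPD3 (0.53), the cytokines IL24 (0.50) and IL11 (0.47), the superoxide dismutase SOD2 (0.44), PMEPA1 (0.40) and the WNT inhibitor DKK1 (0.39), and these 8 had adjusted p-values of 0.00283 to 0.0414 in the authors' deposited table.

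Some genes of the growth factor and interferon responses fell. Of 27 measured immediate early genes, 5 fell, 22 did not pass and none rose (8 passed when adjusted over the list alone, 1 higher and 7 lower). Their median log2 was -0.013, with 13 above 0 and 14 below. The 5 that fell were EGR2, EGR1, FOSB, KLF4 and KLF10, all transcription factors, with EGR1 going from 3384 ± 252 to 1472 ± 23.5 normalized counts (SD, n = 2). In the authors' deposited table the log2 fall was -1.20 for EGR1 (adjusted p = 4.27e-25), -0.71 for FOSB (adjusted p = 0.00233) and -0.68 for KLF4 (adjusted p = 4.41e-05). By limma's cameraPR the list gave an adjusted p of 0.000436 in the lower direction, and adjusted p = 0.665 with an estimated correlation. The call was also lost on the limma values with the preset correlation (adjusted p = 0.0672), in the rank-based form (adjusted p = 0.534) and with log2 as the statistic (adjusted p = 0.0707). Of 40 interferon-stimulated genes, 10 fell and none rose (1 higher and 17 lower adjusted over the list alone), with a median log2 of -0.34. In the authors' deposited table XAF1 fell by 0.79 (adjusted p = 0.000898), the antiviral enzyme RSAD2 by 0.70 (adjusted p = 0.00112), CMPK2 by 0.58 (adjusted p = 0.0338) and the RNA sensor IFIH1 by 0.56 (adjusted p = 0.0325). The cameraPR test of the list gave an adjusted p of 3.71e-14, and an adjusted p = 0.504 with an estimated correlation. Among 24 p53 targets the DNA repair gene XPC and the nuclease gene AEN fell, by 0.43 and 0.36 in the authors' deposited table, and none rose (7 lower adjusted over the list alone). That list ranked lower at an adjusted p of 0.000377 (adjusted p = 0.487 with an estimated correlation).

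Inflammatory genes moved both ways. Of 26 measured members of the NF-kB and cytokine list, IL6, IL8, IL24, IL11 and SOD2 rose while BIRC3, CD83 and RELB fell (6 higher and 4 lower adjusted over the list alone). In the authors' deposited table IL8, a neutrophil chemokine, rose by a log2 of 0.84 (adjusted p = 1.04e-09), while the apoptosis inhibitor BIRC3 fell by 1.12 (adjusted p = 8.68e-14) and the dendritic cell marker CD83 by 0.77 (adjusted p = 0.00167). The list did not pass as a whole (adjusted p = 0.0735). Single members passed in several other lists that did not. These were MMP19 (-1.55 in the authors' deposited table), the androgen-responsive genes ZBTB10 (-0.89) and PMEPA1, the mitochondrial coactivator gene PPARGC1A of the pigmentation list (-1.79), the stress genes CHAC1 (-0.79) and OSGIN1 (-0.80), and KLF10 (-0.42) of the TGF-beta list. EGR1 of the MAPK output and BIRC3 of the dedifferentiation list fell, and DKK1 of the latter rose.

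Genes of energy metabolism and translation had medians slightly above 0, and histone genes had a median below 0. All 45 ribosomal protein genes had a log2 above 0, with a median of 0.23. None passed singly by the authors' p-values, also when adjusted over the list alone, while 18 were higher by limma. Their cameraPR adjusted p was 1.39e-16, against an adjusted p = 0.475 with an estimated correlation. The 32 oxidative phosphorylation genes had a median of 0.25 (adjusted p = 6.52e-11, and adjusted p = 0.475 with an estimated correlation). Again no member passed by the authors' adjusted p, while 12 were higher by limma. The 13 mitochondrially encoded genes had a median of 0.31 (0 passed, 12 higher adjusted over the list alone, 11 higher by limma, adjusted p = 3.82e-10, and adjusted p = 0.456 with an estimated correlation). Mitochondrial reads were 0.193% and 0.211% of SLNCR1 libraries a and b and 0.163% and 0.173% of vector libraries a and b. In both groups the shallower library had the higher share. Over all groups libraries of like depth had similar shares, as given below with delta-conserved. That argues against SLNCR1 as the main cause of the mitochondrial increase. Of 21 replication-dependent histone genes, whose main transcripts lack a poly(A) tail, 7 fell and none rose (12 lower adjusted over the list alone), with a median of -0.79 (adjusted p = 2.36e-12, and adjusted p = 0.091 with an estimated correlation). HIST1H3D fell by 2.06, HIST1H2AG by 1.34, HIST1H4H by 1.31 and HIST1H1D by 1.24 in the authors' deposited table.

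Hypoxia and glycolysis genes had a median of 0.20 (0 of 30 passed, 8 higher adjusted over the list alone, 11 higher by limma, adjusted p = 1.74e-06, and adjusted p = 0.475 with an estimated correlation). Heat shock proteins had a median of 0.19 (0 of 19 passed, 4 higher adjusted over the list alone, 6 higher by limma, adjusted p = 1.84e-05, and adjusted p = 0.48 with an estimated correlation). For the hypoxia and heat shock lists, read depth was not separated from the construct. S phase genes had a median of 0.14 (adjusted p = 0.00121, and adjusted p = 0.521 with an estimated correlation) and genes of G2 and M phase one of 0.13 (adjusted p = 0.000533, and adjusted p = 0.456 with an estimated correlation). No member of either list passed by the authors' p-values, also adjusted over the list alone, while limma called 3 and 4 higher. Among 15 nuclear long noncoding RNAs LINC00511 alone passed by the authors' adjusted p (3 higher adjusted over the list alone, 4 higher by limma, adjusted p = 0.00383, and adjusted p = 0.487 with an estimated correlation). The 16 lists that did not pass had adjusted p-values from 0.0504 to 0.961. Besides the NF-kB list these were the metalloproteinase, androgen-responsive, MAPK output, pigmentation, dedifferentiation, extracellular matrix, TGF-beta, unfolded protein, cholesterol and oxidative stress lists, and the markers of keratinocytes, fibroblasts, endothelium, leukocytes and prostate epithelium, of which only ITGAM passed singly.

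By limma on the recovered libraries 632 genes were higher and 1190 lower, with 295 of the authors' 296 genes among them and in the same direction. The share of higher genes was 34.7% with the main size factors, 21.5% with trimmed-mean scaling and 26.2% with library totals, against 4.4% of the authors' calls. The limma count of 1822 became 317 without vector library a, 4325 without SLNCR1 library a and 761 without SLNCR1 library b.

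**Figure D1:**
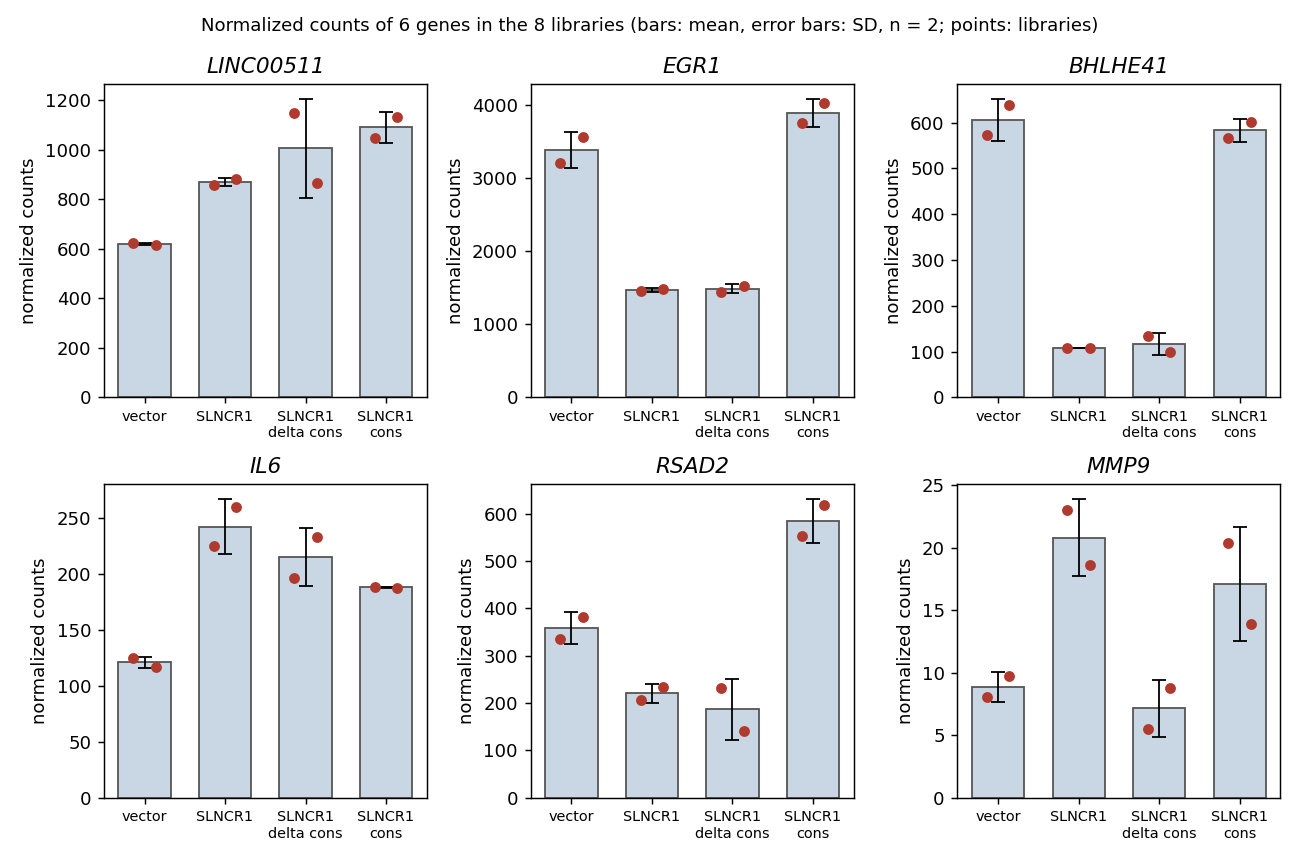
Normalized counts of LINC00511, EGR1, BHLHE41, IL6, RSAD2 and MMP9 in the 4 groups, with bars for the mean of 2 libraries, error bars for the SD and a point for each library. EGR1 averaged 3384 in vector and 3891 with the conserved region, against 1472 with SLNCR1 and 1486 with delta-conserved.

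With the conserved region alone, 5 of the 6 genes that rose were interferon-stimulated genes. Of 34347 genes with a p-value in the authors' deposited table, 6 rose and none fell at an adjusted p under 0.05 (249 higher and 211 lower at an unadjusted p under 0.05). Besides LINC00511 they were RSAD2, IFIT2, OASL, IFI44L and SAMD9, all of them interferon-induced. RSAD2 went from 359 ± 33.6 to 585 ± 46.4 normalized counts, IFIT2 from 496 ± 0.355 to 713 ± 64.8, OASL from 518 ± 3.60 to 728 ± 48.2, IFI44L from 776 ± 20.1 to 1040 ± 61.1 and SAMD9 from 1308 ± 61.4 to 1673 ± 43.9 (SD, n = 2). The authors' deposited table gave log2 fold changes of 0.69, 0.51, 0.47, 0.41 and 0.34 for these 5 genes in that order, with adjusted p-values of 0.000389, 0.032, 0.015, 0.0215 and 0.0351.

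Of 40 measured interferon-stimulated genes 5 rose and 35 did not pass, while 30 were higher adjusted over the list alone. A log2 above 0 was found for 39 of them, with a median of 0.30. The cameraPR adjusted p was 1.01e-68, against an adjusted p = 0.456 with an estimated correlation. The genes next in rank by p belonged to the same response, with XAF1 at a log2 of 0.54 (adjusted p = 0.0695), SAMD9L at 0.39 (0.0996), IFIT3 at 0.37 (0.0884) and PARP14 at 0.27 (0.146) in the authors' deposited table. By limma, LINC00511 was the only gene to pass out of 16058 (874 at an unadjusted p under 0.05), and the 5 interferon genes had adjusted p-values of 0.694 to 0.829. The limma count of 1 became 0 without vector library a, 0 without vector library b and 2 without conserved-region library b.

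Other lists had smaller medians with the conserved region, and LINC00511 was their only member to pass. The NF-kB and cytokine list had a median log2 of 0.17 over 27 members (0 passed, 5 higher adjusted over the list alone, adjusted p = 1.39e-14, and adjusted p = 0.456 with an estimated correlation). Immediate early genes had a median of 0.09 (0 of 27 passed, 3 higher adjusted over the list alone, adjusted p = 1.85e-06, and adjusted p = 0.475 with an estimated correlation). Among the nuclear long noncoding RNAs LINC00511 passed (2 higher adjusted over the list alone, adjusted p = 1.49e-09, and adjusted p = 0.456 with an estimated correlation). In the dedifferentiation list no member passed (1 higher adjusted over the list alone, adjusted p = 1.23e-06, and adjusted p = 0.456 with an estimated correlation).

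A further 12 lists ranked higher with medians of 0.04 to 0.14 and no member past the threshold on any adjustment. Their adjusted p-values were 3.35e-08 for the unfolded protein list, 1.36e-10 for ribosomal proteins, 4.02e-06 for mitochondrially encoded genes, 1.24e-05 for heat shock proteins, 0.000135 for oxidative phosphorylation, 0.000573 for MAPK output and 0.000687 for genes of G2 and M phase. They were 0.00846 for p53 targets, 0.0317 for histones, 0.0333 for androgen-responsive genes and for oxidative stress, and 0.0344 for hypoxia. With an estimated correlation none of these passed (adjusted p = 0.456 to 0.605 with an estimated correlation). Mitochondrial reads were 0.174% and 0.189% of the conserved-region libraries. Libraries of like depth in other groups had similar shares, 0.173% in vector library b and 0.193% in SLNCR1 library a. Read depth was not separated from the construct in the 12 lists. The 11 remaining lists, which were the metalloproteinase, pigmentation, extracellular matrix, TGF-beta, S phase and cholesterol genes and the 5 sets of cell type markers, had adjusted p-values from 0.221 to 0.869. With library totals as the scaling, the medians of the metalloproteinase, matrix, cholesterol and leukocyte lists turned from slightly above 0 to slightly below it.

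With SLNCR1 that lacked its conserved region, the called genes were split about evenly, but nearly all large changes were falls. Of 34744 genes with a p-value in the authors' deposited table, 387 rose and 397 fell against vector at an adjusted p under 0.05. Of those with an absolute log2 of at least 1, 3 rose and 105 fell. Large falls included TSPAN2, from 165 ± 0.542 to 19.6 ± 4.24 normalized counts, NEURL3, from 221 ± 21.6 to 29.8 ± 3.15, and EGR2, from 201 ± 5.41 to 35.4 ± 3.16 (SD, n = 2). Among the increases were IL6, from 121 ± 5.17 to 215 ± 25.9, and fibronectin FN1, from 1168 ± 224 to 1864 ± 160.

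The authors' deposited table gave further log2 falls of -2.86 for ASNSP1, with the same doubt about shared reads, -2.72 for ITGAM, -2.38 for BHLHE41, -2.31 for PLA2G4C and -2.28 for the chloride channel gene BEST1. The activin subunit gene INHBE (-2.18) and the cytokine IL32 (-2.05) also fell, and all 7 had adjusted p-values of 1.12e-07 or lower in the authors' deposited table. Increases in the authors' deposited table included FN1 (0.67, adjusted p = 0.0178), VLDLR, a lipoprotein receptor (0.65, adjusted p = 0.0172), IL24 (0.63, adjusted p = 0.00631) and the secreted hormone STC1 (0.63, adjusted p = 2.72e-05). AKR1C1 (0.57, adjusted p = 0.0174), the hypoxia-induced NDRG1 (0.56, adjusted p = 0.0152) and the prohormone convertase PCSK1 (0.55, adjusted p = 0.00164) followed in the authors' deposited table.

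Some genes of the growth factor and interferon lists fell here too. Of 27 immediate early genes 7 fell, 20 did not pass and none rose (2 higher and 8 lower adjusted over the list alone), with a median log2 of -0.031, 11 above 0 and 16 below. Among those that fell were EGR2, EGR1 at 1486 ± 60.6 normalized counts (SD, n = 2), FOSB and KLF4. EGR1 fell by 1.19 (adjusted p = 2.09e-23) and FOSB by 0.89 (adjusted p = 2.34e-06) in the authors' deposited table. The list's cameraPR adjusted p was 2.28e-05 (adjusted p = 0.563 with an estimated correlation), and the call was also lost in the rank-based form (adjusted p = 0.209). Of 40 interferon-stimulated genes 8 fell and 1 rose (1 higher and 26 lower adjusted over the list alone), with a median log2 of -0.51. In the authors' deposited table IFI27 fell by 1.08 (adjusted p = 0.0148), RSAD2 by 0.95 (adjusted p = 0.0428), XAF1 by 0.94 (adjusted p = 0.000214) and DHX58 by 0.66 (adjusted p = 0.0428). The gene that rose was LGALS3BP, a secreted glycoprotein, at a log2 of 0.33, named after its value was seen. The list's adjusted p was 5.67e-13 (adjusted p = 0.456 with an estimated correlation). Among 24 p53 targets 5 fell and none rose (11 lower adjusted over the list alone, adjusted p = 0.000145, and adjusted p = 0.48 with an estimated correlation), namely SESN1, XPC, BTG2, AEN and DDB2.

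Of the matrix, hypoxia and dedifferentiation lists, 9 of 34, 14 of 30 and 8 of 29 genes rose. Increases of a similar size were not confined to these lists. The 386 genes called higher that were followed in the other comparisons had a median log2 of 0.32 (quartiles 0.28 to 0.36). Their median was 0.26 with SLNCR1 and 0.10 with the conserved region. These medians rise as the read depth of the groups falls, and depth was not separated from the construct. Of the 34 extracellular matrix and mesenchymal genes 9 rose and the repressor ZEB2 fell (16 higher and 2 lower adjusted over the list alone, adjusted p = 3.05e-07, and adjusted p = 0.456 with an estimated correlation). SPARC went from 3142 ± 195 to 4175 ± 187 normalized counts and tenascin TNC from 5705 ± 246 to 7237 ± 110 (SD, n = 2). Collagen COL3A1 went from 3.78 ± 0.348 to 48.0 ± 4.02, a low-count gene that was also at 53.1 in 1 conserved-region library and at 1.99 in the other. Its limma call (adjusted p = 0.0131) was lost without vector library a or b (adjusted p = 0.117 and 0.0738) and without delta-conserved library a or b (adjusted p = 0.0936 and 0.125). Of 30 hypoxia and glycolysis genes 14 rose and none fell (22 higher adjusted over the list alone), with a median of 0.30, an adjusted p of 1.39e-16 and an adjusted p = 0.456 with an estimated correlation. They included BNIP3 (0.45), the glycolytic regulator PFKFB4 (0.45) and lactate dehydrogenase LDHA (0.43) in the authors' deposited table. Of 29 dedifferentiation genes 8 rose and BIRC3 fell (13 higher and 1 lower adjusted over the list alone, adjusted p = 4.78e-05, and adjusted p = 0.456 with an estimated correlation), with SERPINE2 at 0.38 and TGFBI at 0.36 in the authors' deposited table.

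In the metalloproteinase list 4 of 26 members rose, SERPINE2, TIMP3, MMP2 and MMP14, and MMP19 fell by 1.63 in the authors' deposited table (8 higher and 1 lower adjusted over the list alone, adjusted p = 0.0253, and adjusted p = 0.456 with an estimated correlation). Its median log2 was 0.10 and its mean -0.02, and the call was lost on the limma values with the preset correlation (adjusted p = 0.0642). SERPINE2, TIMP3 and MMP2 rose by 0.375, 0.365 and 0.33 in the authors' deposited table. The quartiles of all followed genes called higher were 0.28 to 0.36, and read depth was not separated from the construct. Of 20 androgen-responsive genes NDRG1 and PMEPA1 rose and ZBTB10 fell (the same counts adjusted over the list alone, adjusted p = 0.0228, and adjusted p = 0.456 with an estimated correlation).

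Most ribosomal protein genes and mitochondrially encoded genes rose, while some histone genes fell. Of 45 ribosomal protein genes 28 rose and none fell (44 higher adjusted over the list alone), with a median of 0.31, an adjusted p of 6.71e-33 and an adjusted p = 0.456 with an estimated correlation. Of 13 mitochondrially encoded genes 12 rose (13 adjusted over the list alone), with a median of 0.44, an adjusted p of 1.39e-16 and an adjusted p = 0.456 with an estimated correlation. Mitochondrial reads were 0.210% and 0.228% of delta-conserved libraries a and b. In every group this share was higher in the shallower library b, as were the summed ribosomal protein counts. Libraries of like depth had similar mitochondrial shares whatever the construct. They were 0.173% in vector b and 0.174% in conserved-region a, and 0.189% in conserved-region b and 0.193% in SLNCR1 a. They were 0.211% in SLNCR1 b and 0.210% in delta-conserved a. Summed ribosomal protein counts in these pairs were 53640 and 53770, 58090 and 58040, and 63610 and 61990. For these lists that argues against the construct as the main cause. No vector library was as shallow as the delta-conserved ones, so a smaller effect is not excluded. MT-CO3 went from 961 ± 70.0 to 1335 ± 110 normalized counts and MT-ND4 from 2051 ± 137 to 2848 ± 240 (SD, n = 2). Of 32 oxidative phosphorylation genes 3 rose, ATP5B, ATP5A1 and UQCRC1 (22 adjusted over the list alone, adjusted p = 1.1e-13, and adjusted p = 0.456 with an estimated correlation). Of 21 histone genes 8 fell and none rose (10 lower adjusted over the list alone), with a median of -0.78, an adjusted p of 3.82e-10 and an adjusted p = 0.091 with an estimated correlation. HIST1H1D fell by 1.47 and HIST1H2BD by 1.16 in the authors' deposited table.

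Heat shock genes HSP90AB1, HSPA8 and HSP90AA1 rose among 19 measured (9 higher adjusted over the list alone, adjusted p = 4.93e-07, and adjusted p = 0.456 with an estimated correlation). CKS2 and TOP2A rose among 30 genes of G2 and M phase (5 higher adjusted over the list alone, adjusted p = 1.24e-05, and adjusted p = 0.456 with an estimated correlation). No S phase gene passed by the authors' adjusted p (3 higher adjusted over the list alone, 3 higher by limma, adjusted p = 0.00384, and adjusted p = 0.541 with an estimated correlation). MALAT1 and LINC00657 rose among 15 nuclear long noncoding RNAs (7 higher and 1 lower adjusted over the list alone, adjusted p = 0.000377, and adjusted p = 0.456 with an estimated correlation). The 12 other lists had adjusted p-values from 0.0504 to 0.961. In them DUSP4, PHLDA1 and CCND1 of the MAPK output rose and EGR1 fell, IL6, IL8, IL24, IL11 and SOD2 of the NF-kB list rose while BIRC3, CD83, RELB and NFKB2 fell, SOX10 rose and PPARGC1A fell in the pigmentation list, and the TGF-beta genes PMEPA1, TGFBI, ID1 and INHBA rose while KLF10 fell. Of the unfolded protein list VLDLR, HSP90B1, HSPA5, PDIA6 and DDIT4 rose while CHAC1, DDIT3, ATF3 and ASNS fell. Of the oxidative stress list FTH1, FTL, TXN, NQO1 and MT2A rose while OSGIN1 fell, and no cholesterol gene passed by the authors' adjusted p (1 lower by limma). Cell type markers passed singly only as COL3A1 and ITGAM. The medians of the pigmentation and cholesterol lists turned from slightly above 0 to below it with trimmed-mean scaling and with library totals. For the increases in all of these lists, read depth was not separated from the construct.

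By limma 833 genes were higher and 845 lower, with 772 of the authors' 784 genes among them and in the same direction. The share of higher genes was 49.6%, and 32.2% with trimmed-mean scaling or 30.2% with library totals, against 49.4% of the authors' calls. The limma count of 1678 became 271 without vector library a, 728 without delta-conserved library a and 325 without delta-conserved library b.

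**Figure D2:**
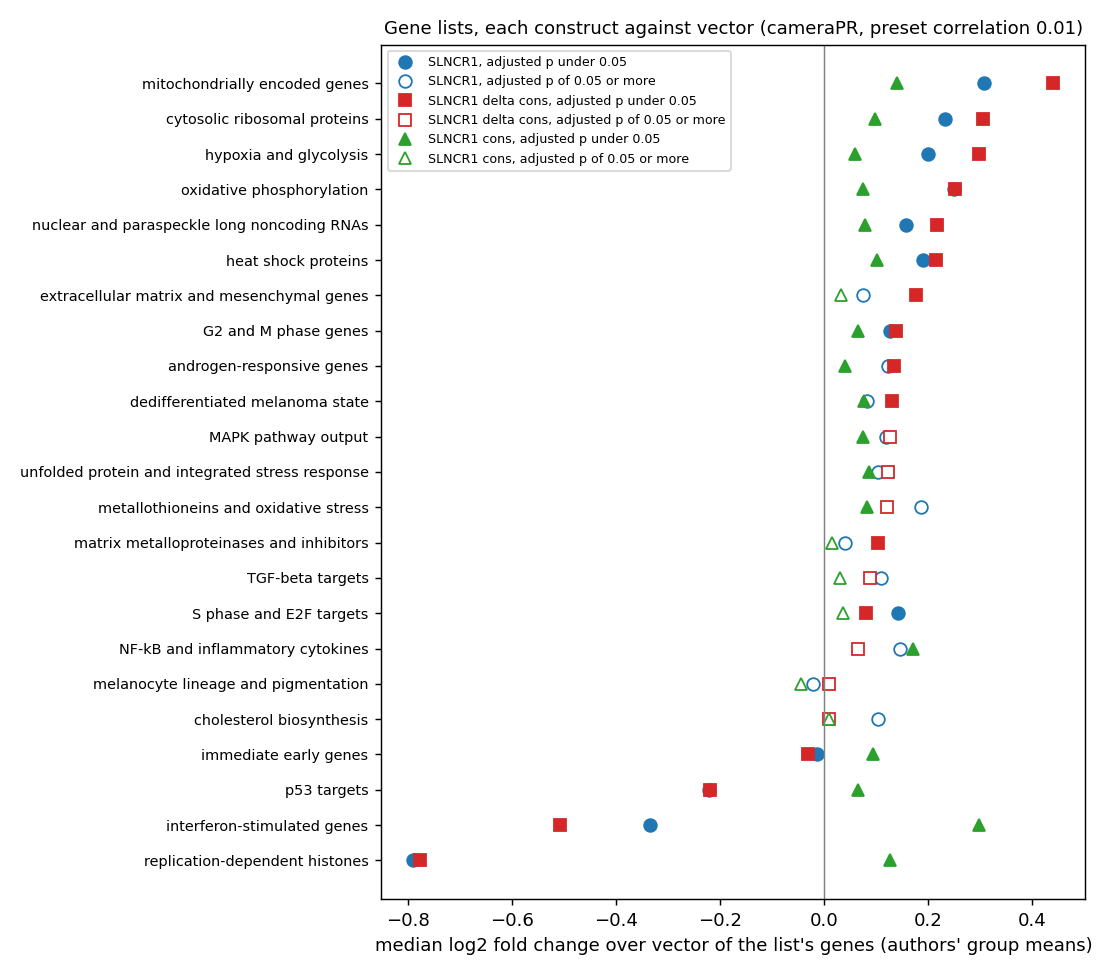
Median log2 fold change over vector of each gene list, cell type markers left out, in the 3 comparisons, with filled points for lists past an adjusted p of 0.05 by cameraPR with the preset correlation. Interferon-stimulated genes lie at 0.30 with the conserved region, -0.34 with SLNCR1 and -0.51 with delta-conserved.

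MMP9, the gelatinase that SLNCR1 has been tied to, was close to the limit of these libraries. It had 10 and 11 reads in the vector libraries, 23 and 17 with SLNCR1, 23 and 14 with the conserved region and 5 and 7 with delta-conserved. The authors' deposited table gave log2 fold changes of 1.23 with SLNCR1 (adjusted p = 0.656), 0.93 with the conserved region (adjusted p = 1) and -0.31 with delta-conserved (adjusted p = 1). POU4F1, the cell cycle inhibitor CDKN1A, the RNA coactivator gene SRA1 and the melanocyte regulator MITF did not pass in any comparison with vector. In the authors' deposited table MITF had log2 values of -0.24, 0.09 and -0.28 with SLNCR1, the conserved region and delta-conserved.

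Most genes called with full-length SLNCR1 were also called with delta-conserved SLNCR1, which had more called genes. Of the 283 genes that fell with SLNCR1, 232 also fell with delta-conserved, against 3.57 for independent lists over the 31458 genes tested in both, and 10 of the 13 that rose also rose, against 0.16 (two-sided Fisher's exact test, p = 1.91e-17 for the genes that rose). The 283 genes had a median log2 of -0.77 with SLNCR1, -0.66 with delta-conserved and 0.06 with the conserved region. With the conserved region SLNCR1 shared LINC00511 alone, and the conserved region and delta-conserved shared none.

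**Figure D3:**
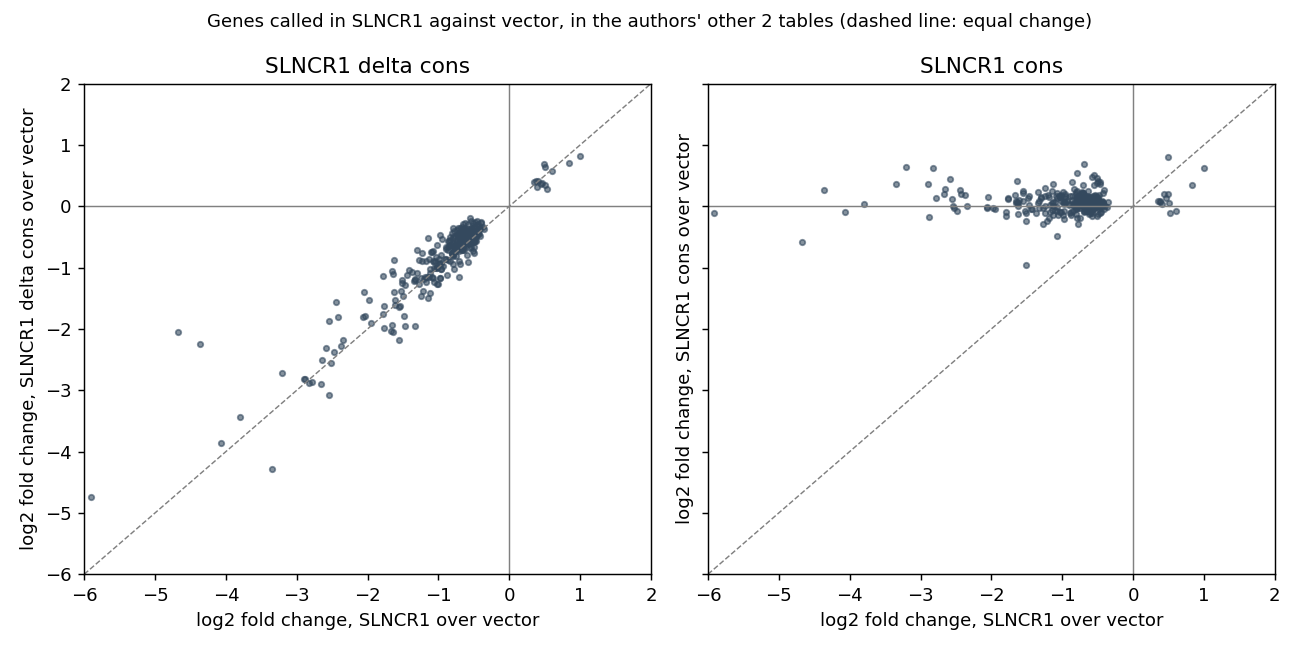
Log2 fold change over vector of the 296 genes called with SLNCR1, plotted for SLNCR1 on the x axis against delta-conserved and against the conserved region on the y axes, each point a gene. All 283 lower genes lie below 0 with delta-conserved, with a median of -0.66, while their median with the conserved region is 0.06.

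All 3 comparisons use the same vector libraries, which adds overlap without any effect. In 20 simulations of unchanged groups against those libraries the mean number of genes called in both comparisons by limma was 0, where the data gave 452 higher and 614 lower genes for SLNCR1 and delta-conserved. The covariance of their log2 fold changes across genes was 0.0719, against 0.0167 in the simulations, a difference of 0.0552. It was 0.0113 for SLNCR1 and the conserved region and 0.0145 for the conserved region and delta-conserved, both below the simulated 0.0167. The 2 vector libraries are too few to split, so part of the excess may come from them. SLNCR1 over vector and delta-conserved over the conserved region have no library in common. There 649 genes were lower in both, against 68.9 for independent lists, and 104 were higher in both, against 7.01. Both comparisons set shallower libraries over deeper ones, so an effect of read depth would be shared. They also come from the same limma fit, with the same variance for each gene, so the lists are not strictly independent.

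Direct tests between constructs used limma on the recovered libraries and were added after the files were seen. Between full-length and delta-conserved SLNCR1 no gene passed at an adjusted p under 0.05, and 1284 of 16058 had an unadjusted p under 0.05. With no member past the threshold, 7 gene lists passed limma's camera with the preset correlation. Hypoxia genes had a median log2 of -0.116 (adjusted p = 1.26e-07), mitochondrially encoded genes -0.155 (5.88e-06), ribosomal proteins -0.078 (6.3e-06), matrix genes -0.083 (6.79e-05) and dedifferentiation genes -0.076 (0.00577), all lower with SLNCR1. Interferon-stimulated genes (0.175, adjusted p = 1.07e-06) and cholesterol genes (0.053, adjusted p = 0.00357) were higher, and none of the 7 passed otherwise (adjusted p = 0.728 with an estimated correlation). The lists lower with SLNCR1 had medians over vector that rose as the read depth of the construct groups fell. The delta-conserved libraries were the shallower, so depth was not separated from the construct for these lists. The 95% interval of the difference was -0.16 to 0.14 (log2) for EGR1, -0.17 to 0.22 for MITF and -0.40 to 0.01 for LINC00511. MMP9 was at 20.8 ± 3.08 normalized counts with SLNCR1 and 7.15 ± 2.30 with delta-conserved (SD, n = 2), a log2 difference of 1.44 with an interval of 0.63 to 2.25 and a limma adjusted p of 0.481. The count of 0 became 1226 without SLNCR1 library a and 2 without SLNCR1 library b.

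The conserved region differed from delta-conserved in 1108 genes by limma, 930 higher and 178 lower. The largest differences were in ITGAM (3.39 ± 0.34, SE), HLF (3.24 ± 0.37), TSPAN2 (3.16 ± 0.22), NEURL3 (3.07 ± 0.17) and ASNSP1 (2.97 ± 0.40), all higher with the conserved region at limma adjusted p-values of 0.000105 or lower. Lower were the lipase inhibitor ANGPTL4 (-1.02 ± 0.26, adjusted p = 0.0193), SHANK1 (-0.76 ± 0.19, adjusted p = 0.0172), IFITM10 (-0.75 ± 0.22, adjusted p = 0.0472), PPFIA4 (-0.75 ± 0.15, adjusted p = 0.00447) and NRN1 (-0.74 ± 0.18, adjusted p = 0.019). EGR1 was higher by 1.39 ± 0.07 (adjusted p = 9.2e-10) and MITF by 0.39 ± 0.09 (adjusted p = 0.0156). Of 40 interferon-stimulated genes 35 were higher and none lower, with a median of 0.84 (adjusted p = 1.26e-40, and adjusted p = 0.728 with an estimated correlation). Of 21 histone genes 12 were higher and none lower (adjusted p = 9.85e-13, and adjusted p = 0.0735 with an estimated correlation). Lower were 14 of 30 hypoxia genes (adjusted p = 6.35e-12, and adjusted p = 0.728 with an estimated correlation). So were 10 of 13 mitochondrially encoded genes (adjusted p = 1.29e-09, and adjusted p = 0.728 with an estimated correlation). The delta-conserved libraries were the shallower. Mitochondrial shares were similar in libraries of like depth whatever the construct, which argues against the construct as the main cause for that list. For the hypoxia genes read depth was not separated from the construct. The count became 430 and 427 without conserved-region library a or b, and 479 and 581 without delta-conserved library a or b.

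Full-length SLNCR1 differed from its conserved region in 1851 genes by limma, 330 higher and 1521 lower. Lower with SLNCR1 were ITGAM (-3.70 ± 0.34, SE), HLF (-3.59 ± 0.37), ASNSP1 (-3.02 ± 0.40), PLA2G4C (-3.02 ± 0.19) and EGR2 (-2.91 ± 0.16), with limma adjusted p-values of 6.87e-05 or lower. Higher were the neuropeptide urocortin UCN (0.90 ± 0.22, adjusted p = 0.0128), IFITM10 (0.89 ± 0.22, adjusted p = 0.0132), DLX4 (0.88 ± 0.22, adjusted p = 0.0148), NMRK1 (0.82 ± 0.22, adjusted p = 0.0217) and S100P (0.77 ± 0.18, adjusted p = 0.0088). LINC00511 was lower by -0.32 ± 0.10 (adjusted p = 0.0396) and MITF by -0.36 ± 0.09 (adjusted p = 0.0172). Of 40 interferon-stimulated genes 34 were lower and none higher, with a median of -0.67 (adjusted p = 6.7e-25, and adjusted p = 0.728 with an estimated correlation), as were 15 of 21 histone genes (adjusted p = 1.68e-10, and adjusted p = 0.0735 with an estimated correlation) and 12 of 24 p53 targets (adjusted p = 5.88e-06, and adjusted p = 0.728 with an estimated correlation). The count became 4025 without SLNCR1 library a, 1145 without SLNCR1 library b, and 707 and 799 without conserved-region library a or b. The call for LINC00511 was lost without conserved-region library a (-0.38, adjusted p = 0.0957) or b (-0.26, adjusted p = 0.247).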

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

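Of the tests below, that of delta-conserved over the conserved region in the genes called with SLNCR1 and that of the interferon list in SLNCR1 libraries were chosen only after the result was seen. The limma tests between constructs were added after the files were seen. The clock gene lists were chosen after clock genes were seen among the falls.

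For 2 of the 3 pairs of constructs, effects over the same vector libraries differed in many genes by direct limma tests. Full-length SLNCR1 against delta-conserved called 0 genes (1284 at an unadjusted p under 0.05), with 1226 without SLNCR1 library a, 2 without SLNCR1 library b and 0 without either delta-conserved library. The conserved region differed from delta-conserved in 1108 genes, with 427 to 581 when either library of either group was left out (430 and 427 without conserved-region library a or b, 479 and 581 without delta-conserved library a or b). Full-length SLNCR1 differed from the conserved region in 1851 genes, with 4025 without SLNCR1 library a, 1145 without SLNCR1 library b, and 707 and 799 without conserved-region library a or b.

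Most genes that changed with full-length SLNCR1 changed with delta-conserved too, and these groups also have the shallowest libraries, lower histone medians (-0.79 and -0.78) and more mitochondrial reads (0.193% to 0.228%, against 0.163% to 0.189% in the other libraries). Thinning all libraries to the smallest kept 99.7% of the median log2 change of the called genes with SLNCR1 and 100.3% with delta-conserved. Thinning lowers all genes in proportion, so it cannot undo a depth effect already in the counts and does not decide on depth. Removing a trend with transcript length and GC content kept at least 93.9% of the median of the called lower genes. That argues against such a trend as the whole cause. A shift of clock phase at harvest was predicted to raise the median of clock genes of the opposite phase. The higher of their medians was -0.254 and no member was above 0.188 in either group. These genes moved both ways, with CRY1 at -0.666 and NPAS2 at 0.131 with SLNCR1, and -0.709 and 0.188 with delta-conserved. With a single harvest time and genes chosen after the falls were seen, this does not decide on clock phase. Action of the conserved region as the whole cause is argued against by delta-conserved over the conserved region, which share no library with SLNCR1 over vector, since the 296 genes showed 91.6% to 99% of the SLNCR1 median there in the 4 pairs of single libraries, and -6.9% with the conserved region over vector. An action of the transcript outside the conserved region is a hypothesis that stays open and untested. Also open are read depth, clock phase and a difference in RNA quality, which the histone values leave possible. The mitochondrial shares followed depth and so do not decide on RNA quality. Separate handling is open too, and is not given in the sources used here.

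Of 40 interferon-stimulated genes 5 rose with the conserved region, 10 fell with SLNCR1, and 8 fell and 1 rose with delta-conserved. The calls of the list were lost in all 3 comparisons (adjusted p = 0.456, 0.504 and 0.456 with an estimated correlation). If the level of the transfected RNA raised these genes and nothing else acted, the list would rise in all 3 constructs. The lowest median was instead -0.508, with delta-conserved. Single libraries had medians over the vector mean of -0.298 and -0.759 with delta-conserved a and b and -0.438 and -0.215 with SLNCR1 a and b. An effect of the level that lowers these genes was not tested. The level was read through LINC00511, whose counted exons are open. A single conserved-region library was not the source, since the medians over the vector mean were 0.252 and 0.384 in its libraries a and b. As the only effect, a response to the conserved region wherever it is carried is argued against by SLNCR1. It holds the region, and its higher library median was -0.215. Within SLNCR1 such a response is not excluded, since the list also fell with delta-conserved, which lacks the region. Directly compared, the list was higher with SLNCR1 than with delta-conserved (median 0.175, camera adjusted p = 1.07e-06 with the preset correlation). That call was lost with an estimated correlation (adjusted p = 0.728). A response to the region alone was not tested. Amounts or purity of plasmid, which may also raise such genes, are not given in the sources used here.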

How the results depend on the processing

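Settings chosen after seeing the data were, for limma against vector, trimmed-mean scaling, library totals and no filter, for direct comparisons, other pseudocounts and library totals, for the target, other pseudocounts, minimum means and no filter, for lists, the preset correlation of 0.05 and the test on limma values, and thinning for all. No paired analysis was possible because the deposited columns carry no replicate numbers, so recovered libraries cannot be tied to them. Count models, the replicate block and fits of only 2 groups, planned for deposited counts, were not run. With 1 library left out, the lone library of a group is assumed to vary like the others, and the fit has 3 residual degrees of freedom. No result that passed in either setting changed sign. Uncalled differences in LINC00511 did, that of SLNCR1 from delta-conserved from -0.195 to 0.006 without delta-conserved a, and that of the conserved region from delta-conserved from 0.128 to -0.078 without delta-conserved b, as did uncalled values of some named genes and medians near 0 of some lists. Over the results for comparisons 120 alternative values stayed alike, 45 counts moved by over 1.5 times, 13 values passed where the main one had not, and 9 failed where it had passed. For named genes 2186 alternative values kept their side of the threshold, 233 lost it and 13 gained it. For called lists 234 kept it and 81 lost it.

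Genes changed with SLNCR1 numbered 96 with an absolute log2 of at least 1 and 1822 by limma. With the conserved region they numbered 10 at an adjusted p of 0.1, 2 at 0.01, 0 with an absolute log2 of at least 1, 10 among means of 10 or more, 22 adjusted over the 3 comparisons together and 1 by limma. With delta-conserved they numbered 405 at 0.01, 108 with an absolute log2 of at least 1 and 1678 by limma. By limma with no filter the counts against vector were 490, 0 and 656, and SLNCR1 had 3159 at 0.1. Leaving out each library gave 317 (without vector a) to 4325 (without SLNCR1 a) for SLNCR1, with 761 without SLNCR1 b, 0 (without vector a or b) to 2 (without conserved-region b) for the conserved region, and 271 (without vector a) to 1268 (without vector b) for delta-conserved, with 728 and 325 without delta-conserved a or b. SLNCR1 against delta-conserved gave 0 to 1226 (without SLNCR1 a), 2 without SLNCR1 b, and 1 with a minimum mean of 1, with thinning and at 0.1. The conserved region against delta-conserved gave 602 with no filter, 1695 at 0.1 and 427 to 581 with each library left out (430 and 427 without conserved-region a or b, 479 and 581 without delta-conserved a or b). SLNCR1 against the conserved region gave 890 with no filter, 2826 at 0.1 and 707 (without conserved-region a) to 4025 (without SLNCR1 a), with 1145 without SLNCR1 b and 799 without conserved-region b. Of the 45 list calls 0 remained with an estimated correlation, 37 calls were made with a preset of 0.05 and 32 with log2 as the statistic. Overlaps at an unadjusted p under 0.01 were 654, 5 and 10, against 242, 1 and 0.

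By limma LINC00511 with SLNCR1 was 0.487 with no filter (adjusted p = 0.0535), and 0.465 to 0.506 with each library left out, missing the threshold without vector a (0.499, adjusted p = 0.062). With the conserved region it was 0.81 with no filter (adjusted p = 0.293) and 0.752 to 0.873 with each library left out, missing it without vector a (0.823) or b (0.807). With delta-conserved all limma settings passed, at 0.682 (also with a minimum mean of 1 or 50 and no filter), 0.683 and 0.68 with pseudocounts of 0.25 and 4, 0.639 with trimmed-mean scaling, 0.624 with library totals, 0.661 thinned and 0.48 to 0.885 with each library left out. SLNCR1 against the conserved region gave -0.31 with library totals (adjusted p = 0.0507), -0.323 with no filter (adjusted p = 0.18) and -0.384 to -0.264 with each library left out, missing the threshold without conserved-region a (adjusted p = 0.0957) or b (adjusted p = 0.247). Other than fewer samples or more genes tested, the cause of these changes was not tested. Of the named genes other than LINC00511 called with delta-conserved, 34 of 82 kept their call in every alternative, with 40 lost without vector a and 43 without delta-conserved b. It was 37 of 41 with SLNCR1 and 0 of 5 with the conserved region. Depth limits genes of few reads, such as MMP9.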

Other observations

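The clock gene lists here and their tests were chosen only after the falls of HLF and BHLHE41 had been seen. Genes driven by the circadian clock fell with SLNCR1 and with delta-conserved. Of 12 such genes 11 fell in each of these groups, all but BHLHE40, with a median log2 of -1.57 with SLNCR1 and -1.46 with delta-conserved, and none passed with the conserved region, where the median was -0.02. The period gene PER1 averaged 1891 normalized counts in vector, 614 with SLNCR1, 1979 with the conserved region and 654 with delta-conserved. PER2 averaged 491, 117, 487 and 141 in that order, and NR1D1, a nuclear receptor that represses ARNTL, 1664, 545, 1808 and 546. By limma the log2 change with SLNCR1 was -1.62 ± 0.07 (SE) for PER1, -2.06 ± 0.10 for PER2, -1.61 ± 0.07 for NR1D1, -1.22 ± 0.10 for DBP and -1.28 ± 0.10 for TEF. The sum over the 12 genes was 9144 and 9584 normalized counts in the vector libraries, 4418 and 4253 with SLNCR1, 9546 and 9782 with the conserved region, and 4624 and 4591 with delta-conserved. Of 5 genes of the opposite phase CRY1 fell in both groups in the authors' deposited tables, and ARNTL, CLOCK, NPAS2 and NFIL3 did not pass there. By limma the log2 change of ARNTL was -0.51 ± 0.11 (SE) with SLNCR1 and -0.46 ± 0.11 with delta-conserved. That of NFIL3 was -0.26 ± 0.09 and -0.39 ± 0.09, and that of NPAS2 0.13 ± 0.07 and 0.19 ± 0.07, in the same order.

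Interferon-stimulated genes summed to 39110 and 40580 normalized counts in the vector libraries, 32150 and 35820 with SLNCR1, 46620 and 51060 with the conserved region, and 35490 and 29180 with delta-conserved. The vector pair was the closest and the delta-conserved pair the farthest apart, and differences within groups were not tested. Histone transcripts summed to 2314 and 2323 in the vector libraries, 1466 and 1566 with SLNCR1, 2574 and 2637 with the conserved region, and 1494 and 1549 with delta-conserved.

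COL3A1 was found at about the same high level in only some libraries. It was at 4.02 and 3.53 normalized counts in the vector libraries, 4.0 and 4.38 with SLNCR1, 53.1 and 1.99 with the conserved region, and 50.8 and 45.2 with delta-conserved.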
